A study of Mus musculus with 9 samples.

How the data were processed

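RNA of small intestine epithelial cells from naïve mice was sequenced as 9 libraries, 3 per group, with an Illumina TruSeq kit, per the labels. The extraction text of the same labels names a collagen-induced arthritis model, which the treatment label does not, and the control label does not say which floxed gene the controls carry. The authors deposited a table of raw counts per gene for 43629 genes, with coordinates, which were used as deposited. CASAVA, Bowtie 0.12.2 and the build mm10 are named in the submitters' processing notes; the counting program, its annotation and its strand setting are not given in the sources used here, so overlapping and antisense genes and near-identical copies are uncertain. Of the identifiers, 42462 were also in the GENCODE M21 annotation and 33497 of those had the same start and end.

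Total counts ran from 20959964 to 40391453 per library. Library pairs of one group had a chi-square per gene of at least 43.8, where counting noise alone gives 1, so none was taken for 1 library deposited 2 times. The lowest value between groups was 17.6, for control replicate 1 with HIF1α∆IEC replicate 1. Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr with the group kept 15486 genes, libraries were scaled by TMM, and the quasi-likelihood F test of all 9 libraries by group, with 6 residual degrees of freedom, gave two-sided p-values adjusted by Benjamini-Hochberg, called under 0.05. The common biological coefficient of variation was 0.353. CPM are TMM-scaled, errors of CPM are SDs of 3 libraries, errors of log2 fold changes are SEs, and log2 CPM used a prior count of 2.

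Before the data were examined, 43 gene lists were fixed, and 42 with at least 5 tested genes each were tested with camera (limma 3.58.1; preset correlation 0.01), adjusted over the lists within a comparison; the list of sex-linked genes was read by values only. Camera with an estimated correlation and fry were alternatives. Named genes followed a rule fixed at the same time: Hif1a, Epas1 and Arnt; up to 10 rising and 10 falling called genes of largest fold, at a mean CPM of at least 1 and with no overlap between groups (none qualified); up to 4 members of smallest p of a described list, with Slc2a1, Pgk1, Ldha, Slc11a2, Cybrd1, Slc40a1, Vegfa, Ankrd37, Pdk1, Cldn15, Cldn2 and Tjp1; and, with under 10 calls, the 10 genes of smallest unadjusted p. Genes called by DESeq2 alone were named after their values were seen, and some genes that the rule names are not reported here.

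Alternatives fixed at the same time were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no count filter, a minimum CPM of 1 in 3 libraries, a fit of the 6 libraries compared, the replicate number as a block, glmTreat against a fold change of 1.2, and leaving out each library. Added after seeing the data were the removal of HIF1α∆IEC replicate 2 and HIF2α∆IEC replicate 1, a term for sex read from Xist and 4 Y-linked genes, and limma-voom with quality weights. The fits were tested on simulated counts with 200 changed genes, each gene drawn independently and without the structure across the real samples. For HIF1α∆IEC against control, where 15182 genes were tested, edgeR recovered 11.9% of 2-fold, 73.1% of 4-fold and 95.5% of 8-fold changes and called 4 unchanged genes, and DESeq2 recovered 31.3%, 83.6% and 97.0% and called 42 unchanged genes of 15486 tested.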

Results

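Messenger RNA of small intestine epithelial cells was counted per gene in 9 mouse libraries, 3 labelled HIF1α∆IEC, 3 labelled HIF2α∆IEC and 3 labelled as littermate controls. HIF1α (gene Hif1a) and HIF2α (gene Epas1) are the oxygen-regulated subunits of the hypoxia-inducible transcription factors, which pair with ARNT, and ∆IEC in the labels marks a loss in intestinal epithelial cells. Total counts ran from 21461212 to 24706678 in the controls, from 20959964 to 29931812 in HIF1α∆IEC and from 31576340 to 40391453 in HIF2α∆IEC. The labels speak of mice but do not say that each library came from a separate animal. The p-values therefore measure only the spread between these samples, which may be in part technical.

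HIF1α∆IEC replicate 2 and HIF2α∆IEC replicate 1 stood apart from the other libraries. Transcripts of the mitochondrial genome made up 12.2% and 10.8% of their counts, against 5.04% in control replicate 1 and 6.74% in control replicate 2, the lowest and highest controls. T and intraepithelial lymphocyte markers in HIF2α∆IEC replicate 1 lay 2.77 log2 units above the control mean, erythroid genes 3.83 above and Paneth cell markers at -1.39. In HIF1α∆IEC replicate 2 the erythroid genes lay 1.66 above the control mean and the lymphocyte markers 0.63 above, values exceeded by erythroid genes in HIF2α∆IEC replicate 2 (1.75) and lymphocyte markers in HIF1α∆IEC replicate 3 (0.89). Xist and 4 Y-linked genes placed 3 of 3 controls as male, and 1 male and 2 females in each of the other groups. The male of HIF2α∆IEC was replicate 1, so without it that group is all female against male controls. HIF1α∆IEC replicate 2 was female. A sex term rests on males against females within the ∆IEC groups, where these 2 libraries enter, so it cannot separate sex from them. A male and a female library are not repeats of 1 animal, so each ∆IEC group held more than 1 animal. Pearson correlations of log2 CPM ran from 0.930 to 0.987 within groups and from 0.935 to 0.987 between them.

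The targeted genes were read first. Hif1a (ENSMUSG00000021109, mm10 chromosome 12, 73901375 to 73947530) had 22.6, 64.2 and 18.0 CPM in the HIF1α∆IEC libraries, against 16.0, 19.9 and 21.1 in the controls and 34.9, 15.1 and 22.5 in HIF2α∆IEC. Epas1 (ENSMUSG00000024140, chromosome 17, 86753907 to 86833410) had 36.1, 11.2 and 11.6 CPM in the HIF2α∆IEC libraries, against 32.7, 14.5 and 21.1 in the controls and 29.8, 18.5 and 22.3 in HIF1α∆IEC. Neither gene passed the test: the log2 fold change of Hif1a in HIF1α∆IEC against control was 0.88 ± 0.46 (SE; edgeR adjusted p = 0.999), and that of Epas1 in HIF2α∆IEC against control -0.21 ± 0.46 (edgeR adjusted p = 1.00). Single libraries decided both values: without HIF1α∆IEC replicate 2 Hif1a was at 0.066, and without HIF2α∆IEC replicate 1 Epas1 was at -0.98. Epas1 turned to 0.12 without control replicate 1, to 0.066 and 0.053 without HIF2α∆IEC replicates 2 and 3, and to 0.34 with a sex term. Arnt lay between 27.4 and 41.5 CPM in the 9 libraries. A count over a whole gene need not read the deleted exons, which the labels do not name, so this is a weak check. The libraries are called by their labels below, and every direction rests on those labels.

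**Figure D1:**
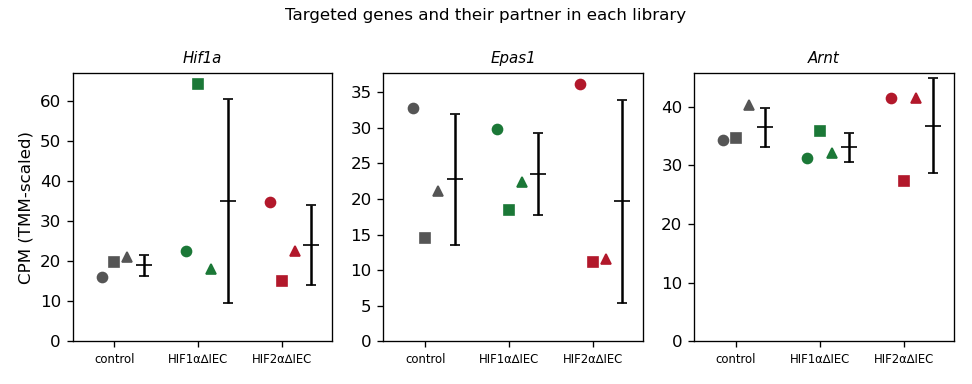
CPM (vertical axis, TMM-scaled) of Hif1a, Epas1 and Arnt in each library of the control, HIF1α∆IEC and HIF2α∆IEC groups; circles, squares and triangles are replicates 1, 2 and 3, and the black mark and bar are the mean and SD of 3 libraries. Hif1a in HIF1α∆IEC spans 18.0 to 64.2 CPM and Epas1 in HIF2α∆IEC spans 11.2 to 36.1 CPM, both overlapping the controls.

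The comparison of HIF1α∆IEC with control asks which transcripts differ when epithelial HIF1α is lost. Narf, a hypoxia-inducible gene, had 18.9 ± 2.83 CPM in HIF1α∆IEC against 40.4 ± 3.65 in the controls (SD, n = 3 each), 2.14-fold less. Ankrd37, another HIF target, had 0.536 ± 0.411 CPM against 3.02 ± 1.61, and Ak4, a mitochondrial adenylate kinase, 0.375 ± 0.141 against 1.29 ± 0.462. For each of these 3 genes the HIF1α∆IEC libraries all lay below the controls, but no gene passed over all 15486 tested. The edgeR quasi-likelihood test called 0 genes, with 600 at an unadjusted p under 0.05 (450 higher, 150 lower; 774.3 were expected by chance) and a smallest adjusted p of 0.999. DESeq2 called 2 genes, C1qb and C1qc, and limma-voom called 0. On simulated counts for this comparison DESeq2 called 42 unchanged genes and edgeR 4. There DESeq2 also recovered 21 genes changed 2-fold, 56 changed 4-fold and 64 changed 8-fold. Unchanged genes thus made up a larger share of its simulated calls than the threshold of 0.05 allows. The 42 itself is no count of false calls among the 2 genes. The groups did not overlap for 8.32% of the tested genes, where chance gives 10%. Without control replicate 3, edgeR called Gm6969 alone (adjusted p = 0.00014; 0.00014 to 1.00 over the alternatives). Of 61 named fold changes in this comparison, 27 turned or moved by over 1.5 times without some single library, 21 of them without HIF1α∆IEC replicate 2.

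Of the 38 tested hypoxia-inducible targets, 17 had a positive and 21 a negative fold change, and the list did not pass camera (adjusted p = 0.0738). Over all genes 0 of them passed; adjusted over the list alone 2 did, Narf at -1.09 ± 0.25 and Ankrd37 at -2.45 ± 0.63 on the log2 scale. Ak4 was at -1.78 ± 0.56 and Ddit4 at 0.45 ± 0.27. Vegfa, the vascular growth factor, was at -0.42 ± 0.36, and Pdk1, which restrains pyruvate oxidation, at -0.46 ± 0.34. Vegfa was at -0.89 without HIF1α∆IEC replicate 1 and at -0.097 without replicate 2. The glycolysis genes fell as a group, with 21 of 26 negative (camera adjusted p = 0.0228; adjusted p = 0.799 with an estimated correlation). Pgk1 was at -0.46 ± 0.24, Aldoc at -0.74 ± 0.35 and Hk2 at -0.38 ± 0.26. Gbe1, the glycogen branching enzyme on the same list, was at 0.90 ± 0.56, or 0.042 without HIF1α∆IEC replicate 2. Slc2a1, the glucose transporter, was at 0.08 ± 0.30 and Ldha, lactate dehydrogenase, at -0.05 ± 0.31. Of the glycolysis genes 0 passed over all genes and 0 adjusted over the list alone. The glycolysis call was lost without the 2 libraries that stood apart (adjusted p = 0.821) and with a sex term (0.741).

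Iron handling and tight junction genes did not pass as groups (camera adjusted p = 0.99 for each). Of their members 13 of 26 and 14 of 30 were positive, and 0 passed over all genes or adjusted over the list alone. The medians were -0.02 and -0.03 and the means 0.08 and 0.06. Slc11a2, the apical iron importer, was at -0.19 ± 0.26, Cybrd1, the duodenal ferric reductase, at 0.28 ± 0.39, and Slc40a1, the iron exporter, at 0.10 ± 0.73. The ferritin gene Ftl1 was at 0.42 ± 0.21, Ireb2 at 0.65 ± 0.44, Slc39a14 at -0.37 ± 0.26 and Slc25a37 at -0.38 ± 0.29. On the tight junction and barrier list Cldn15 was at 0.12 ± 0.26, Cldn2 at -0.49 ± 0.30, Tjp1 at 0.53 ± 0.34, Cgnl1 at 0.73 ± 0.42 and Cldn7 at 0.37 ± 0.23. Pkp2, a desmosome gene on that list, was at -0.45 ± 0.28. Without HIF1α∆IEC replicate 2 Ireb2 was at -0.22, Slc40a1 at -0.33, Slc39a14 at -0.16, Slc25a37 at -0.16, Cgnl1 at 0.36 and Tjp1 at 0.049. Without replicate 1 Slc25a37 was at -0.84 and Cybrd1 at -0.053.

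Camera called 13 of 42 lists in HIF1α∆IEC against control, 9 up and 4 down, and 0 with an estimated correlation, where the smallest adjusted p was 0.465. Cytosolic ribosomal protein genes rose as a group (64 of 75 positive, adjusted p = 2.59e-16; adjusted p = 0.61 with an estimated correlation), with Rplp1 at 1.17 ± 0.38 and Rpl36 at 0.69 ± 0.23. Oxidative phosphorylation genes rose (51 of 58 positive, adjusted p = 6.55e-15; adjusted p = 0.58 with an estimated correlation), with the complex I subunits Ndufa2 at 0.63 ± 0.20 and Ndufa6 at 0.88 ± 0.30. The mitochondrially encoded transcripts rose too (13 of 13 positive, adjusted p = 5.49e-09; adjusted p = 0.58 with an estimated correlation), with mt-Co3 at 1.41 ± 0.40 and mt-Nd3 at 1.26 ± 0.44. Without replicate 2 of HIF1α∆IEC mt-Nd3 was at 0.40 and Rplp1 at 0.60. The mitochondrial list stood at 0.28, 1.61 and 0.48 from the control mean in HIF1α∆IEC replicates 1, 2 and 3. The ribosomal call was lost with a sex term (adjusted p = 0.0833).

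Among cell type lists, stromal and muscle markers rose (13 of 15 positive, adjusted p = 8.03e-09; adjusted p = 0.465 with an estimated correlation), with the collagens Col6a1 at 1.83 ± 0.55 and Col3a1 at 1.89 ± 0.61. T and intraepithelial lymphocyte markers rose (30 of 31, adjusted p = 0.000516; adjusted p = 0.912 with an estimated correlation), with Trbc2 at 1.43 ± 0.72 and Cd2 at 1.13 ± 0.69. Goblet cell markers rose (15 of 21, adjusted p = 0.002; adjusted p = 0.58 with an estimated correlation), with Guca2a at 1.12 ± 0.33 and Tpsg1 at 0.94 ± 0.29. Distal intestine markers rose (21 of 25, adjusted p = 1.28e-05; adjusted p = 0.465 with an estimated correlation), with Fgf15, an ileal bile acid signal, at 2.15 ± 0.76. Immediate early and heat shock genes rose (27 of 30, adjusted p = 1.82e-05; adjusted p = 0.58 with an estimated correlation), with Junb at 0.72 ± 0.24 and Klf2 at 1.43 ± 0.54. Antigen presentation genes rose (18 of 22, adjusted p = 7.65e-05; adjusted p = 0.68 with an estimated correlation), with H2-Eb1 at 0.68 ± 0.27 and H2-Aa at 0.81 ± 0.34. Fgf15 was at 1.29 without HIF1α∆IEC replicate 2, and without replicate 3 H2-Eb1 was at 0.35 and H2-Aa at 0.50.

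PPARα targets and fatty acid oxidation genes fell (21 of 32 negative, adjusted p = 0.0115; adjusted p = 0.799 with an estimated correlation), with Cpt1a, which imports fatty acids into mitochondria, at -0.44 ± 0.20. Cholesterol synthesis genes fell (19 of 25, adjusted p = 0.0176; adjusted p = 0.63 with an estimated correlation), with Cyp51 at -0.58 ± 0.31 and Acat2 at -0.42 ± 0.22. Xenobiotic metabolism genes fell (29 of 43, adjusted p = 0.00385; adjusted p = 0.857 with an estimated correlation), with Ces1f at -0.89 ± 0.36 and Ugt1a6a at -0.84 ± 0.45. Without control replicate 3 Ces1f was at -0.29. No member of these 13 lists passed over all genes; adjusted over the list alone 4 stromal genes did and 0 in each of the other 12. With a sex term the xenobiotic list turned upward (adjusted p = 0.000755), and the PPARα call was lost (0.25), as it was without the 2 libraries that stood apart (0.0824).

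The genes of smallest unadjusted p in this comparison did not pass either (edgeR adjusted p = 0.999 each). C1qb and C1qc, complement genes of macrophages, were at 2.42 ± 0.54 and 2.38 ± 0.54, with 2.65, 9.50 and 11.2 CPM of C1qb in the HIF1α∆IEC libraries against 1.42, 1.22 and 1.71 in the controls. The predicted gene Gm6969 was at -4.97 ± 1.09 but had 69.1 and 51.3 CPM in control replicates 1 and 2 and 0.683 in control replicate 3. Lrrn4 was at 3.18 ± 0.82. Lower were Tma7-ps at -1.15 ± 0.26, RP23-456B9.24 at -1.98 ± 0.49, RP23-346I1.1 at -1.90 ± 0.48 and Gm29666 at -2.33 ± 0.59, loci of pseudogene or clone names whose reads may be shared with other copies.

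The comparison of HIF2α∆IEC with control asks the same of epithelial HIF2α. Pxdn, a peroxidase of the extracellular matrix (ENSMUSG00000020674, mm10 chromosome 12, 29938036 to 30017658), had 16.0 ± 6.58 CPM in HIF2α∆IEC against 0.923 ± 0.508 in the controls (SD, n = 3 each). Its neighbour Acp1, a phosphatase (chromosome 12, 30893326 to 30911612), had 43.4 ± 6.87 CPM against 11.2 ± 3.85, and the metallothionein Mt1 684 ± 183 against 227 ± 42.9. For these 3 genes all HIF2α∆IEC libraries lay above all controls, yet none passed. The log2 fold changes were 4.10 ± 0.53 for Pxdn (edgeR adjusted p = 0.119), 1.95 ± 0.37 for Acp1 (1.00) and 1.59 ± 0.25 for Mt1 (0.296). The edgeR test called 0 genes, with 287 at an unadjusted p under 0.05 (172 higher, 115 lower; 774.3 expected by chance). DESeq2 called 5, Pxdn, Mt1 and Acp1 higher and Gm6969 and Mical3 lower, and limma-voom called 0. On simulated counts DESeq2 called 32 unchanged genes here and edgeR 5. DESeq2 also recovered 15 simulated 2-fold, 61 4-fold and 64 8-fold changes, so the 32 is no count of false calls among the 5. The share of unchanged genes among its simulated calls was again over 0.05. The groups did not overlap for 5.55% of the tested genes, where chance gives 10%. Without HIF2α∆IEC replicate 1, edgeR called Pxdn alone (adjusted p = 0.016; 8.55e-13 to 1.00 over the alternatives), and without control replicate 3 Gm6969 alone (adjusted p = 0.000113). Of 71 named fold changes here, 47 turned or moved by over 1.5 times without some single library, 33 of them without HIF2α∆IEC replicate 1.

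**Figure D2:**
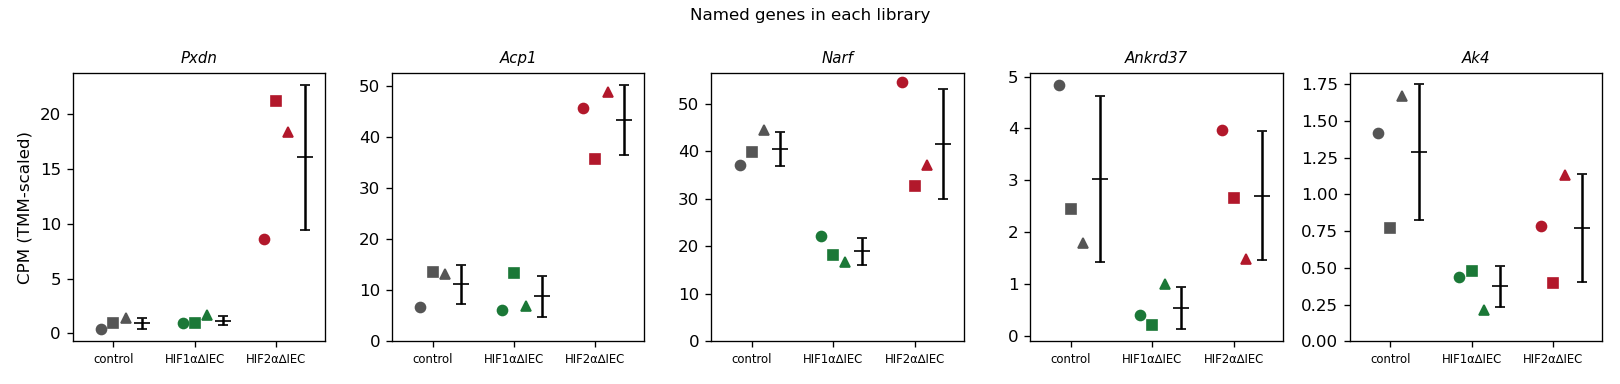
CPM (vertical axes, TMM-scaled, each starting near 0) of Pxdn, Acp1, Narf, Ankrd37 and Ak4 in each library by group; circles, squares and triangles are replicates 1, 2 and 3, and black marks and bars are the mean and SD of 3 libraries. Pxdn lies between 8.60 and 21.1 CPM in HIF2α∆IEC and at most 1.64 CPM in the other 6 libraries, and Narf lies between 16.7 and 22.1 CPM in HIF1α∆IEC and at least 32.6 CPM in the others.

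Iron handling genes in HIF2α∆IEC did not pass as a group (camera adjusted p = 0.784, 15 of 26 positive, 0 passing over all genes or adjusted over the list alone). Slc11a2 was at -0.18 ± 0.26, Cybrd1 at -0.29 ± 0.39 and Slc40a1 at 0.04 ± 0.73, the last with 39.4, 5.07 and 6.19 CPM in the HIF2α∆IEC libraries. Abcg2 was at 0.63 ± 0.43, Ireb2 at 0.55 ± 0.44, Hmox1 at -0.46 ± 0.41 and the transferrin receptor Tfrc at 0.30 ± 0.29. Hypoxia-inducible targets did not pass (adjusted p = 0.404, 24 of 38 positive, 0 over all genes and 0 adjusted over the list alone), but did with a sex term (up, adjusted p = 0.00994). Angptl4, an inhibitor of lipoprotein lipase, was at 1.23 ± 0.33, Plod2 at 1.68 ± 0.78, Ddit4 at 0.47 ± 0.27, Nt5e at 1.49 ± 0.87, Vegfa at 0.15 ± 0.36, Ankrd37 at -0.16 ± 0.57 and Pdk1 at -0.09 ± 0.34. Nt5e had 29.7, 2.91 and 2.17 CPM in the HIF2α∆IEC libraries against 1.95, 6.46 and 3.91 in the controls. Nt5e turned to -0.69, Slc40a1 to -1.52 and Vegfa to -0.026 without HIF2α∆IEC replicate 1. Glycolysis genes did not pass (adjusted p = 0.219, 19 of 26 negative, 0 over all genes and 0 adjusted over the list alone), with Eno3 at 0.51 ± 0.34, Pgm1 at 0.31 ± 0.25, Pkm at -0.27 ± 0.28, Tpi1 at -0.24 ± 0.27, Slc2a1 at -0.15 ± 0.30, Pgk1 at 0.04 ± 0.24 and Ldha at -0.26 ± 0.31. Tight junction genes did not pass (adjusted p = 0.205, 18 of 30 negative, 0 over all genes and 0 adjusted over the list alone), with Cldn15 at -0.11 ± 0.26, Cldn2 at -0.12 ± 0.30, Tjp1 at -0.47 ± 0.34, Pard3 at -0.38 ± 0.22, Cldn4 at 0.67 ± 0.43 and Magi1 at -0.27 ± 0.21. Without HIF2α∆IEC replicate 1 Cldn4 was at 0.082 and Pgm1 at 0.084, without replicate 2 Cybrd1 was at -0.077, and without control replicate 1 Pkm was at 0.011 and Ldha at 0.025.

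Camera called 18 of 42 lists in HIF2α∆IEC against control, 14 up and 4 down, and 0 with an estimated correlation. It called 7 up and 7 down without the 2 libraries that stood apart, and 7 and 8 without control replicate 2. Every other library left out singly kept more lists up than down. Tuft cell markers fell (26 of 27 negative, adjusted p = 4.35e-23; adjusted p = 0.367 with an estimated correlation), with Sh2d7 at -1.38 ± 0.53, or -0.65 without control replicate 1. The list stood at 0.01 from the control mean in HIF2α∆IEC replicate 1 and at -1.39 in replicate 3, and the controls spread from -0.64 to 0.69. Its call was lost with a sex term (adjusted p = 0.0723). Stromal and muscle markers rose (15 of 15, adjusted p = 6.18e-26; adjusted p = 0.0589 with an estimated correlation), with Col1a2 at 2.10 ± 0.58 and Col6a1 at 2.23 ± 0.54, at 1.40 ± 0.179 and 1.31 ± 0.342 CPM. Erythroid genes rose (5 of 6, adjusted p = 1.39e-11; adjusted p = 0.182 with an estimated correlation), with the globins Hbb-bt at 4.26 ± 1.18 and Hbb-bs at 3.39 ± 0.94. Hbb-bt was at 2.78 and Hbb-bs at 1.81 without HIF2α∆IEC replicate 1. Distal intestine markers rose (22 of 25, adjusted p = 8.42e-06; adjusted p = 0.182 with an estimated correlation), with Fabp6, the ileal bile acid binding protein, at 1.34 ± 0.47 and Mep1a at 0.37 ± 0.21. The interferon list was called down (adjusted p = 0.0249; adjusted p = 0.833 with an estimated correlation) although its median and mean log2 fold changes were 0.05 and 0.15 and 26 of 47 members were positive. With a sex term that call was lost (adjusted p = 0.26). Oas1g was at -0.77 ± 0.27 and Oas1a at -0.59 ± 0.22.

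**Figure D3:**
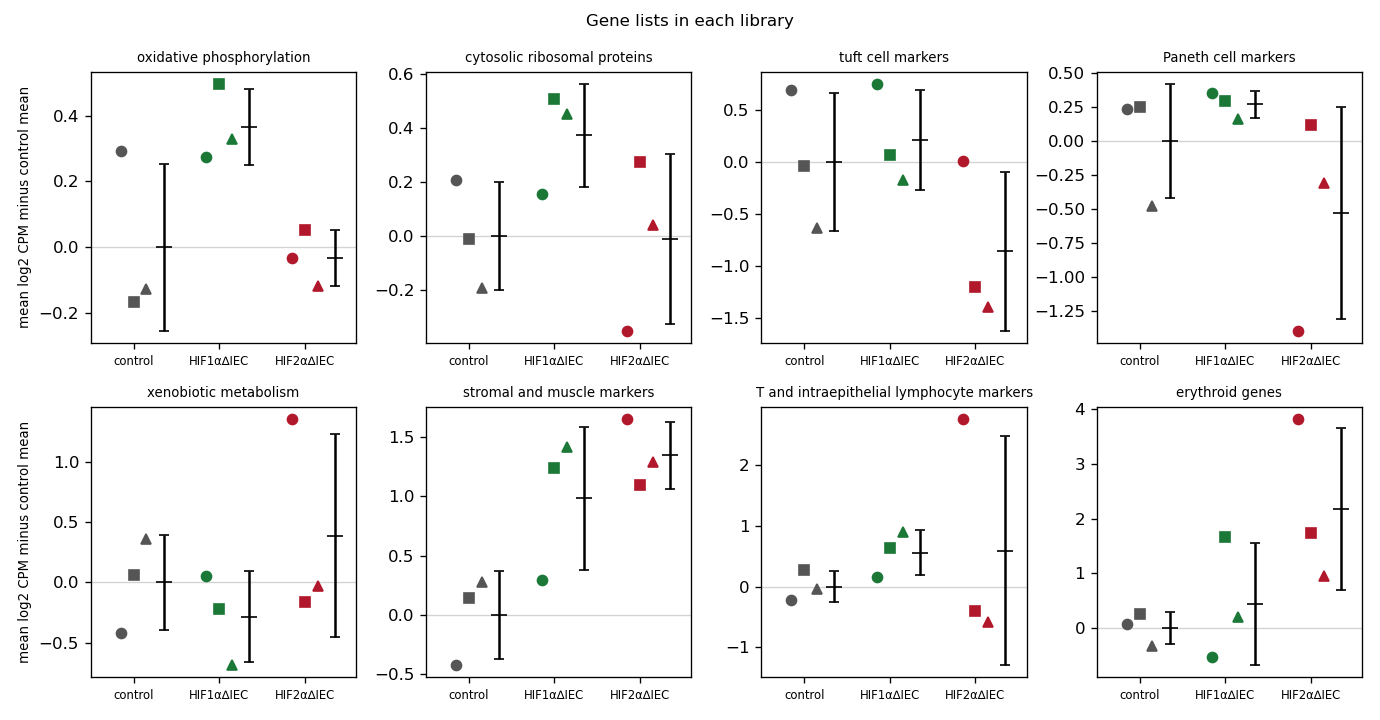
Mean log2 CPM of the members of 8 gene lists minus the mean of the controls (vertical axes), in each library by group; circles, squares and triangles are replicates 1, 2 and 3, and black marks and bars are the mean and SD of 3 libraries. HIF2α∆IEC replicate 1 lies apart for lymphocyte markers at 2.77 and Paneth cell markers at -1.39, and oxidative phosphorylation lies at 0.29 in control replicate 1, within the HIF1α∆IEC range of 0.27 to 0.50.

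The other 13 calls were lost or turned without the 2 libraries that stood apart. That fit, like the one without HIF2α∆IEC replicate 1 alone, sets 2 female HIF2α∆IEC libraries against 3 male controls. What that fit calls in the libraries left therefore cannot be told apart from sex. HIF2α∆IEC replicate 1 was male like the controls and lay outside their range, in the called direction, in each of these 13 lists. Its T and intraepithelial lymphocyte markers stood at 2.77 against -0.23 to 0.27 in the controls. Sex does not give that excess, which is the value of 1 library. Without HIF2α∆IEC replicate 1 alone 5 of the 18 lists kept their call and 2 were called the opposite way. Xenobiotic metabolism genes rose (43 of 43, adjusted p = 1.83e-08; adjusted p = 0.545 with an estimated correlation), with Ces1g at 1.01 ± 0.35. Bile acid genes rose (11 of 12, adjusted p = 0.000298; adjusted p = 0.371 with an estimated correlation), with Cyp3a11 at 2.46 ± 0.91. PPARα targets rose (26 of 32, adjusted p = 0.000219; adjusted p = 0.568 with an estimated correlation), with Pdk4 at 1.68 ± 0.70. Lipid absorption genes rose (26 of 31, adjusted p = 0.0249; adjusted p = 0.833 with an estimated correlation), with Fabp2 at 0.85 ± 0.39. Immediate early genes rose (24 of 30, adjusted p = 0.00203; adjusted p = 0.568 with an estimated correlation), with Fos at 1.22 ± 0.52 and Fosb at 1.36 ± 0.68. Circadian clock genes rose (19 of 19, adjusted p = 0.0321; adjusted p = 0.568 with an estimated correlation), with Per1 at 1.08 ± 0.54 and Cry2 at 0.55 ± 0.31. Antigen presentation genes rose (15 of 22, adjusted p = 0.0393; adjusted p = 0.833 with an estimated correlation), with H2-Ab1 at 0.60 ± 0.29 and H2-Aa at 0.60 ± 0.33. Myeloid markers rose (17 of 21, adjusted p = 0.000148; adjusted p = 0.568 with an estimated correlation), with C1qb at 1.34 ± 0.53 and Csf1r at 1.23 ± 0.52. Paneth cell markers fell (18 of 23, adjusted p = 9.95e-11; adjusted p = 0.439 with an estimated correlation), with Defa3 at -1.72 ± 0.60 and Ang4 at -1.12 ± 0.45. Stem cell markers fell (20 of 24, adjusted p = 9.12e-06; adjusted p = 0.545 with an estimated correlation), with Gkn3 at -1.07 ± 0.39 and Nkd1 at -0.79 ± 0.49. Without HIF2α∆IEC replicate 1 Cyp3a11 was at 0.26, Pdk4 at 0.43, Fabp2 at 0.29, Fos at 0.55, Fosb at 0.24, Per1 at 0.43 and Cry2 at 0.25, and without control replicate 2 Defa3 was at -0.66.

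T and intraepithelial lymphocyte markers rose (31 of 31, adjusted p = 6.52e-11; adjusted p = 0.568 with an estimated correlation), with Cd69 at 2.32 ± 0.90 and Xcl1 at 2.16 ± 0.86. Enterocyte markers rose (29 of 32, adjusted p = 0.00394; adjusted p = 0.833 with an estimated correlation), and so did mitochondrially encoded transcripts (11 of 13, adjusted p = 0.0462; adjusted p = 0.833 with an estimated correlation), with mt-Atp8 at 1.89 ± 0.83 and mt-Co3 at 0.81 ± 0.40. Cd69 was at 0.28, Xcl1 at 0.35 and mt-Co3 at 0.30 without HIF2α∆IEC replicate 1, and without replicate 2 mt-Atp8 was at 0.35. These 3 lists were called down without the 2 libraries that stood apart (adjusted p = 7.47e-11, 2.73e-05 and 0.0202). In all 18 lists 0 members passed over all genes; adjusted over the list alone 7 stromal and 5 erythroid genes did and 0 in each of the other 16. Further genes of small unadjusted p, none passing, were Acer1, a ceramidase, at 1.16 ± 0.27, the transporter gene Slc6a20b at 1.99 ± 0.50, Lrrn4 at 3.29 ± 0.80, Gm6472 at -1.11 ± 0.26, Mical3 at -1.54 ± 0.35 and Gm6969 at -5.07 ± 1.09.

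The direct comparison of HIF2α∆IEC with HIF1α∆IEC tests the difference between the groups itself. Narf had 41.4 ± 11.6 CPM in HIF2α∆IEC against 18.9 ± 2.83 in HIF1α∆IEC (SD, n = 3 each), and Ankrd37 had 3.97, 2.65 and 1.48 CPM against 0.399, 0.211 and 0.998. Hypoxia-inducible targets rose as a group (26 of 38 positive, camera adjusted p = 0.0258; adjusted p = 0.511 with an estimated correlation), with 0 passing over all genes and 1, Narf at 1.13 ± 0.25, adjusted over the list alone. Ankrd37 was at 2.29 ± 0.62, Angptl4 at 1.07 ± 0.33, Ak4 at 1.06 ± 0.56, Vegfa at 0.57 ± 0.36 and Pdk1 at 0.38 ± 0.34. Vegfa was at 0.25 without HIF1α∆IEC replicate 2, and Pdk1 was at 0.18 and Ak4 at 0.67 without HIF2α∆IEC replicate 3. The call of this list was lost without the 2 libraries that stood apart (adjusted p = 0.509). The edgeR test called 0 genes, with 1021 at an unadjusted p under 0.05 (357 higher, 664 lower; 774.3 expected by chance). DESeq2 called 15 and limma-voom 0, and on simulated counts DESeq2 called 39 unchanged genes here and edgeR 13. DESeq2 also recovered 18 simulated 2-fold, 59 4-fold and 63 8-fold changes, so the 39 is no count of false calls among the 15. The share of unchanged genes among its simulated calls was over 0.05 here too. Without HIF2α∆IEC replicate 1 edgeR called Pxdn (adjusted p = 0.0272; 4.55e-11 to 0.705 over the alternatives). The groups did not overlap for 10.4% of the tested genes, where chance gives 10%. Of 56 named fold changes here, 31 turned or moved by over 1.5 times without some single library, 20 of them without HIF1α∆IEC replicate 2.

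Camera called 12 of 42 lists here, 5 up and 7 down, and 0 with an estimated correlation (smallest adjusted p = 0.497). Tuft cell markers were lower in HIF2α∆IEC, with 27 of 27 negative (adjusted p = 3.14e-15; adjusted p = 0.497 with an estimated correlation), Gng13 at -1.96 ± 0.61 and Pou2f3, the tuft lineage factor, at -1.47 ± 0.52. Oxidative phosphorylation genes were lower (54 of 58, adjusted p = 5.99e-15; adjusted p = 0.497 with an estimated correlation), with Uqcrq at -1.01 ± 0.29 and Cox6b1 at -1.04 ± 0.30. Ribosomal protein genes were lower (62 of 75, adjusted p = 9.67e-16; adjusted p = 0.497 with an estimated correlation), with Rplp1 at -1.49 ± 0.38 but Rpl29 at 5.47 ± 1.52, or 0.74 without HIF2α∆IEC replicate 3. Mitochondrially encoded transcripts were lower (12 of 13, adjusted p = 0.000649; adjusted p = 0.689 with an estimated correlation), with mt-Nd3 at -1.63 ± 0.44 and mt-Nd5 at -1.06 ± 0.43. Paneth cell markers (22 of 23, adjusted p = 6.94e-10), pancreatic acinar genes (6 of 11, adjusted p = 0.0376) and endothelial markers (6 of 8, adjusted p = 0.028) were lower, each with adjusted p = 0.497 with an estimated correlation. Ang4 was at -1.60 ± 0.45, Clps at -2.03 ± 0.59, Rnase1 at -0.82 ± 0.31, Prox1 at -1.26 ± 0.46 and Esam at -0.88 ± 0.42. Without HIF1α∆IEC replicate 2 mt-Nd3 was at -0.77, mt-Nd5 at -0.49, Prox1 at -0.60 and Rplp1 at -0.92.

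Xenobiotic metabolism genes were higher (40 of 43, adjusted p = 3.76e-11), as were PPARα targets (27 of 32, adjusted p = 5.39e-07), cholesterol synthesis genes (19 of 25, adjusted p = 0.00924) and erythroid genes (5 of 6, adjusted p = 0.000158), each with adjusted p = 0.497 with an estimated correlation. The carboxylesterase Ces1f was at 1.56 ± 0.37, Pdk4 at 2.39 ± 0.72, Msmo1 at 0.76 ± 0.28, Cyp51 at 0.77 ± 0.31, Alas2 at 2.73 ± 0.81 and Hba-a2 at 2.87 ± 1.15. Pdk4 was at 1.17 and Hba-a2 at 1.11 without HIF2α∆IEC replicate 1. No member of the 12 lists passed over all genes; adjusted over the list alone 4 erythroid genes, 2 xenobiotic genes, 1 mitochondrial transcript and 1 hypoxia target did, and 0 in each of the other 8. The xenobiotic, Paneth and endothelial calls were lost without the 2 libraries that stood apart (adjusted p = 0.0702, 0.0881 and 0.0702).

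Iron, tight junction and glycolysis lists did not pass in this comparison (camera adjusted p = 0.85, 0.384 and 0.326), and 0 of their members passed over all genes or adjusted over the list alone. Slc11a2 was at 0.01 ± 0.26, Cybrd1 at -0.56 ± 0.39, Slc40a1 at -0.05 ± 0.73, Slc25a37 at 0.46 ± 0.29, Ftl1 at -0.31 ± 0.21 and Aco1 at 0.26 ± 0.20. Tjp1, which encodes a scaffold protein of tight junctions, had 31.2 ± 7.75 CPM against 62.6 ± 29.7. Cgnl1 was at -0.67 ± 0.42, Dsc2 at -0.58 ± 0.37, Cldn7 at -0.35 ± 0.23, Cldn15 at -0.24 ± 0.26 and Cldn2 at 0.37 ± 0.30. Pgk1 was at 0.51 ± 0.24, Pgm1 at 0.48 ± 0.25, Pfkl at 0.41 ± 0.23, Gbe1 at -0.78 ± 0.55, Slc2a1 at -0.23 ± 0.30 and Ldha at -0.21 ± 0.31. Without HIF1α∆IEC replicate 2 Gbe1 turned to 0.073 and Dsc2 to 0.16, and Cgnl1 was at -0.28. Cybrd1 was at -0.23 without HIF1α∆IEC replicate 1 and Cldn2 at -0.022 without HIF2α∆IEC replicate 3. The smallest unadjusted p values belonged to Pxdn at 3.77 ± 0.52, Tma7-ps at 1.75 ± 0.27, Acp1 at 2.31 ± 0.37, RP23-456B9.24 at 2.88 ± 0.50, Gm6472 at -1.47 ± 0.26, Akr1b8 at 2.12 ± 0.42, Gm24270 at -1.97 ± 0.42, the kinase gene Hipk2 at -1.62 ± 0.35 and Slc6a20b at 2.29 ± 0.50, none passing.

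No gene was called in both comparisons with control by edgeR, which called 0 in each; the counts at an unadjusted p under 0.05 were 600 and 287, and 36 genes at that level were higher in both, 7 lower in both and 2 opposite. Independent lists would share 5 and 1.11, and unchanged groups simulated against the same controls shared 96.2 and 60.1. The sizes of the simulated lists are not given here, so these counts may not compare like with like. Without the 2 libraries that stood apart 47 genes were higher in both, 32 lower in both and 14 opposite, with r = 0.250. DESeq2 and limma-voom also called 0 in both. The log2 fold changes of both comparisons correlated across genes at Pearson r = 0.330, against 0.503 in the simulation, and their covariance was 0.0747 against 0.116, a difference of -0.0417. Genes are not independent replicates, and with 3 controls no split leaves 2 on each side, so part of any sharing may come from the shared controls. The correlation and covariance lay below the lowest of 20 simulations (0.491 and 0.114). They therefore show no sharing beyond what shared controls gave in that simulation.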

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

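The tests of the quality-weighted fits, of the chromosome segment, of the hypoxia targets across splits, and all those without the 2 libraries that stood apart or with a sex term were chosen after the data were seen. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. HIF1α∆IEC against control called 0 genes and 13 lists; other splits called up to 1 gene and 22 lists, and 10 and 4 of the 10 splits gave as many. HIF2α∆IEC against control called 0 genes and 18 lists; other splits called up to 2 genes and 28 lists, and 10 and 7 gave as many. HIF2α∆IEC against HIF1α∆IEC called 0 genes and 12 lists; other splits called up to 0 genes and 22 lists, and 10 and 7 gave as many. Quality-weighted limma-voom called 1931, 114 and 2909 genes, other splits up to 5414, 592 and 580, and 4, 2 and 1 of the splits gave as many. The split of HIF1α∆IEC replicates 1 and 3 with control replicate 1 against the rest had 3279 genes at an unadjusted p under 0.05 against 600 for the real one, which points to a structure of the samples that crosses the groups. So does that of HIF2α∆IEC replicates 1 and 3 with HIF1α∆IEC replicate 2, with 4642 against 1021. Both splits part the libraries by the sign of the Spearman correlation of their deviations from the gene means with gene length. It was -0.14 in control replicate 1, -0.20 in HIF1α∆IEC replicates 1 and 3 and -0.18 in HIF2α∆IEC replicate 2. It was 0.067 in HIF1α∆IEC replicate 2, 0.13 and 0.11 in HIF2α∆IEC replicates 1 and 3, and 0.16 and 0.19 in control replicates 2 and 3. The cause was not tested.

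Narf, Ankrd37 and Ak4 lay below the controls in all 3 HIF1α∆IEC libraries. Without the 2 libraries that stood apart the fold change nearest 0 among the 3 was -1.09, so the difference did not rest on them alone. As all 3 HIF1α∆IEC libraries lay below the controls, removing 1 could hardly change this. With a sex term the value nearest 0 was -0.77. The male HIF1α∆IEC library lay below the male controls too. For Narf and Ankrd37 the female HIF2α∆IEC libraries lay above all HIF1α∆IEC libraries, so sex alone does not give the values of these 2 genes. The term cannot separate sex from the libraries that stood apart. A part of sex in these differences therefore stays open, and for Ak4 sex stays open. Of the 38 hypoxia targets 5 lay below all controls, but 2 of the 9 other splits set as many apart in one direction, up to 9, and the splits are too few for a share under 0.05. A loss of HIF1α activity, which the group labels name, may be the cause and was not tested separately.

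Pxdn and Acp1 lay above all other libraries in HIF2α∆IEC. Without the 2 libraries that stood apart the smaller of their log2 fold changes was 1.93, so the difference did not rest on them alone. As all 3 HIF2α∆IEC libraries lay above the rest, removing 1 could hardly change this, and it left females against male controls. With a sex term the value was 1.77. HIF2α∆IEC held 1 male and HIF1α∆IEC 2 females, so sex alone does not give this pattern. Both genes lie within 1 Mb on chromosome 12, and of the 22 other tested genes within 2 Mb 3 had an unadjusted p under 0.05 (13.6% against 1.82% elsewhere; one-sided Fisher's exact p = 0.00733). Those were Gpr22 at 2.32, Rps7 at 0.66 and, lower, Lamb1. A candidate explanation is a chromosome segment of another strain shared by these mice, found and tested on the same data; it stays open beside an effect of HIF2α, which was not tested separately.

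Oxidative phosphorylation and ribosomal protein genes had medians of 0.38 ± 0.04 and 0.39 ± 0.05 in HIF1α∆IEC (bootstrap SE over genes). These SEs treat the genes as independent, although the estimated correlation was 0.34 and 0.54, and leave out the spread between libraries. Neither list passed camera with an estimated correlation (adjusted p = 0.58 and 0.61). Control replicate 1 (0.29 and 0.21) lay above HIF1α∆IEC replicate 1 (0.27 and 0.16). Both lists hold short genes, at a median of 1710 and 1535 bases against 3348 over all tested genes. The shortest of 5 length classes lay above its mean over libraries in 3 of 3 HIF1α∆IEC libraries, 1 of 3 controls and 1 of 3 HIF2α∆IEC libraries. In HIF1α∆IEC replicate 2 the longest class lay above its mean too, at 0.22 against 0.12 for the shortest. The sign of the correlation with length, given above, crossed the groups. Removing the trend with length left 0.26 ± 0.05 and 0.30 ± 0.06, and the larger share left was 75.8%, so that trend was not the whole cause. It was fitted on the annotated gene length, so a length bias of another form stays open. Without the 2 libraries that stood apart at least 77.0% of each median was left, which argues against those libraries as the whole cause. With a sex term 82.4% of the oxidative phosphorylation median and 25.8% of the ribosomal one were left. The term cannot separate sex from the 2 libraries that stood apart, so sex stays open for both lists.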

How the results depend on the processing

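The sex term, the quality weights and the removal of the 2 libraries that stood apart were chosen after the data were seen. The sex term cannot separate sex from those libraries, and their removal leaves HIF2α∆IEC all female against male controls. Over the 3 comparisons 188 log2 fold changes of named genes were recomputed under the alternatives. Of 3749 values 3538 kept their direction and side of the threshold, 119 kept their direction and passed, and 92 in 34 of the results changed sign; the cause was not tested. In HIF1α∆IEC against control, where edgeR called 0 genes, 1 was called without a count filter (Gm6969), 2 by DESeq2 and 1931 with quality weights. In HIF2α∆IEC against control 5 were called without a filter, 5 by DESeq2, 114 with quality weights and 1, Pxdn, without the 2 libraries. In HIF2α∆IEC against HIF1α∆IEC 10 were called without a filter, 15 by DESeq2 and 2909 with quality weights. Called in both comparisons with control were 1 gene without a filter and 19 with quality weights. With RLE or upper-quartile scaling, limma-voom, a minimum CPM of 1, glmTreat, a sex term and the 6 libraries compared alone, 0 genes were called in each comparison. The replicate numbers did not pair the libraries: 3 of 9 same-numbered pairs had deviations correlated over 0.1 (from -0.37 to 0.24), 0 libraries correlated best with their own number in both other groups, and for 4 of the 9 the highest correlation over both was with their own number. With the replicate number as a block 1 gene (Xist), 2 genes (Pxdn and Xist) and 0 genes were called, and 1 in both comparisons with control. With the block 15, 18 and 15 lists were called, 13, 17 and 12 of them among those called without it. In HIF2α∆IEC against control the circadian clock list did not pass (adjusted p = 0.0885) and antimicrobial and epithelial defence genes did (0.0142, down). Called with the block alone were also Paneth and acinar genes in HIF1α∆IEC against control (0.0155 and 0.0489, up), and defence, stem cell and stromal genes in HIF2α∆IEC against HIF1α∆IEC (0.0409 each; down, down and up). Camera calls of lists, 13, 18 and 12, became 0 with an estimated correlation and 0 with fry in each comparison. With a sex term 24 lists were called in HIF1α∆IEC against control, 9 of them among the 13 and 1 turned, 23 in HIF2α∆IEC against control, 16 among the 18, and 13 in HIF2α∆IEC against HIF1α∆IEC, 12 among the 12. Lists called without the 2 libraries were 12, 14 and 19, 11, 5 and 8 of them among the 13, 18 and 12, and 3 turned in HIF2α∆IEC against control. Leaving out 1 library at a time gave 11 to 19 lists in HIF2α∆IEC against HIF1α∆IEC, 0 to 1 genes in each comparison and 0 to 1 genes in both comparisons with control. Without the 2 libraries that stood apart, Ldha was at 0.17, Ireb2 at -0.22, Slc11a2 at 0.015 and Slc40a1 at -0.33 in HIF1α∆IEC against control. With a sex term, Ldha was at 0.082 and Vegfa at 0.025 in HIF1α∆IEC against control. By limma-voom with quality weights, Ldha was at 0.35, Ireb2 at -0.20, Slc11a2 at 0.076 and Slc40a1 at -0.20 in HIF1α∆IEC against control. With 1 library left out in HIF1α∆IEC against control, Epas1 ranged from -0.19 to 0.37, Slc2a1 from -0.13 to 0.28 and Ldha from -0.32 to 0.20. Ireb2 ranged from -0.22 to 0.94, Slc11a2 from -0.39 to 0.015 and Cybrd1 from -0.053 to 0.48. Slc40a1 ranged from -0.33 to 0.60 and Cldn15 from -0.025 to 0.34. Without the 2 libraries that stood apart, Arnt was at -0.059, Slc2a1 at 0.058, Pgk1 at -0.055, Nt5e at -0.69, Vegfa at -0.025, Slc40a1 at -1.52 and Cldn2 at 0.044 in HIF2α∆IEC against control. With a sex term, Epas1 was at 0.34, Ankrd37 at 0.012, Cybrd1 at 0.048 and Atp7b at 0.062 in HIF2α∆IEC against control. By limma-voom, Arnt was at -0.012 and Slc40a1 at -0.44 in HIF2α∆IEC against control. By limma-voom with quality weights, Slc2a1 was at 0.035, Ldha at 0.00056, Nt5e at -0.86, Cybrd1 at 0.039, Slc40a1 at -1.20, Cldn15 at 0.0013 and Cldn2 at 0.16 in HIF2α∆IEC against control. With the replicate block, Slc40a1 was at -0.34 in HIF2α∆IEC against control. With 1 library left out in HIF2α∆IEC against control, Epas1 ranged from -0.98 to 0.12, Arnt from -0.085 to 0.18 and Pkm from -0.44 to 0.011. Tpi1 ranged from -0.39 to 0.046, Slc2a1 from -0.36 to 0.058 and Pgk1 from -0.086 to 0.24. Ldha ranged from -0.43 to 0.025, Nt5e from -0.69 to 1.98 and Vegfa from -0.026 to 0.30. Ankrd37 ranged from -0.53 to 0.33, Pdk1 from -0.37 to 0.11 and Slc40a1 from -1.52 to 0.54. Cldn15 ranged from -0.25 to 0.13 and Cldn2 from -0.51 to 0.058. Without the 2 libraries that stood apart, Slc11a2 was at -0.19 and Dsc2 at 0.078 in HIF2α∆IEC against HIF1α∆IEC. By limma-voom with quality weights, Hif1a was at 0.10, Slc11a2 at -0.18 and Dsc2 at 0.096 in HIF2α∆IEC against HIF1α∆IEC. With 1 library left out in HIF2α∆IEC against HIF1α∆IEC, Hif1a ranged from -0.85 to 0.28, Epas1 from -1.004 to 0.015 and Gbe1 from -1.16 to 0.073. Slc2a1 ranged from -0.45 to 0.0027, Ldha from -0.43 to 0.058 and Slc11a2 from -0.19 to 0.21. Slc40a1 ranged from -1.59 to 0.38, Dsc2 from -0.83 to 0.16 and Cldn2 from -0.022 to 0.58. On counts simulated without the structure across the real samples, edgeR recovered 73.1% of 4-fold and 11.9% of 2-fold changes. These values are for HIF1α∆IEC against control, over 15182 genes tested. Changes of 2-fold were therefore mostly not detectable. In the real libraries Pxdn did not pass in HIF2α∆IEC against control at a log2 fold change of 4.10 (edgeR adjusted p = 0.119). The 0 calls therefore do not exclude changes of 4-fold or more.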

Other observations

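The tests around Hif1a and Epas1 were planned before their result was seen. The metallothioneins, which bind zinc and copper, had values on opposite sides of the controls in HIF1α∆IEC: Mt1 had 411 ± 34.3 CPM against 227 ± 42.9 in the controls, and Mt2 34.0 ± 7.74 against 82.4 ± 20.9 (SD, n = 3 each). The log2 fold changes were 0.85 ± 0.24 and -1.28 ± 0.34, and neither passed over all genes (edgeR adjusted p = 0.999). In HIF2α∆IEC Mt2, named there after its values were seen, had 76.3 ± 33.1 CPM. The list of copper and zinc genes did not pass camera in HIF1α∆IEC (adjusted p = 0.605) or in HIF2α∆IEC (0.0522, or 0.0198 with a sex term); adjusted over the list alone 2 members (Mt1 and Mt2) and 1 member (Mt1) passed, and over all genes 0. Antimicrobial and epithelial defence genes did not pass in either comparison with control (adjusted p = 0.96 and 0.0576), nor did proliferation genes (0.96 and 0.175), enteroendocrine markers (0.96 and 0.34) or the unfolded protein response (0.732 and 0.87). Proliferation genes were called down in both with a sex term (adjusted p = 1.91e-06 and 8.67e-08). Without the 2 libraries that stood apart they were called up in HIF2α∆IEC (0.0266), where the libraries left were female and the controls male.

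Genes linked to a targeted allele may carry variants of the strain in which it was made, a hypothesis tested on the neighbours of each targeted gene. Within 5 Mb of Hif1a 1 of 68 tested genes had an unadjusted p under 0.05 in HIF1α∆IEC against control (1.47% against 3.89% elsewhere; one-sided Fisher's exact p = 0.932). Within 5 Mb of Epas1 0 of 39 did in HIF2α∆IEC against control (1.86% elsewhere; one-sided Fisher's exact p = 1). The control label names a floxed allele without saying of which gene. Controls that carry the same allele would share its flanks, so these values exclude nothing and the hypothesis stays open.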
